A study of Drosophila melanogaster with 96 samples.

How the data were processed

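The series measured polyadenylated RNA from whole bodies of individual adult Drosophila melanogaster of the laboratory strain w1118. Virgin flies of both sexes were kept singly in the wells of a feeding plate, given a chemically defined liquid food, starved on buffered saline, and then refed the same food with a dye and dimethyl sulfoxide (DMSO), a solvent used to carry drugs, at 4 levels from none to 0.4% by volume. Flies were taken after 0, 2, 4 or 8 h of refeeding. Each of the 32 groups of sex, DMSO level and time held 3 flies, each with its own stranded library, 96 in all. Replicates were separate flies, so the p-values measure the spread between individual flies. Per the labels' protocols, each time point had its own feeding plate, so time cannot be told apart from the plate or the clock time of collection, and each RNA was pooled with RNA of distantly related insects before library preparation.

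The deposited files held whole-number counts per gene, 1 file per library, which the authors made before deposit. CASAVA 1.8.2, bcl2fastq 1.8, STAR 2.4.2a, TopHat2 2.1.0 and HTSeq 0.6.1p1 were named, with no roles, per the submitters' processing notes. The genome build is not given in the sources used here, and no coordinates are reported. Each file listed 17370 genes by FlyBase identifier, 96 spike-in transcripts and 5 summary lines. A symbol was found for 17155 identifiers; the 215 others held 2.55% of the gene counts. Summary lines took a median of 12.9% of a library (8.73 to 23.3%), of which reads outside any gene took a median of 6.22% and reads shared between genes 6.47%. They and the spike-ins stayed out of library sizes and tests. Genes with near-identical copies, among them the Turandot, Attacin, Jonah protease and ribosomal RNA genes, could have lost reads to the shared class or to a copy, so their values are uncertain to that extent. The 117 ribosomal RNA genes and pseudogenes took a median of 17.6% of the gene counts (4.81 to 51.4%).

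Gene counts per library ran from 958896 to 9215800, with a median of 4777950. In the shallowest library 3 counts equal 3.13 CPM (counts scaled by library size). Floors and the bounds made from them cover counting error only. No pair of the 96 replicate pairs held identical values, and the smallest chi-square per degree of freedom between replicates was 4.71, so each library counted as 1 replicate.

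Groups were taken from the sample titles, which also give the sequencing run. All female libraries came from 1 run. In males the libraries without DMSO at 0 and 2 h, and 2 of 3 at 4 h, came from that run and the others from another, so male DMSO comparisons at those times are confounded with the run. Male times on food without DMSO are also confounded with the run, wholly for 8 h against 0 h and in part for 4 h against 0 h. The title of 1 male library (0 h, 0.4% DMSO, replicate 2) gives 0 h while its characteristics give 8 h; the title was used.

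Tests used edgeR's quasi-likelihood test (edgeR 4.0.16, R 4.3.3) with TMM scaling, edgeR's default expression filter over groups and Benjamini-Hochberg adjustment within each comparison at 0.05. Each sex was fitted with all of its 48 libraries as 16 groups, which tested 10060 genes in females and 12644 in males; 12069 genes were tested between sexes and 13061 in the fit of all 96 libraries. The common biological coefficient of variation was 0.403 in females and 0.239 in males. DMSO was tested as any of 3 levels against none, as each level against none, as a mean slope over 2, 4 and 8 h in females, and as a change of the effect from 0 h. Time was tested against 0 h over 4 foods in females (12 flies against 12) and over the 3 foods with DMSO in males (9 against 9). Sex was tested on food without DMSO at 0 and 2 h (6 flies against 6). Log2 fold changes are given with standard errors (SE). CPM values are TMM-normalised within a sex, unless called unnormalised.

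Gene lists were written from general knowledge of the fly: genes of fasting under FOXO and REPTOR, sugar response, carbohydrate digestion, fat synthesis, glycolysis, ribosome biogenesis, ribosomal proteins, digestive proteases, cytochrome P450s, glutathione S-transferases, UDP-glycosyltransferases, oxidative stress, sulfur and methionine metabolism, heat shock, Turandot stress peptides, immunity, the unfolded protein response, cell death, the clock, nutrient hormones, neuronal activity, JNK and JAK-STAT signalling, and markers of egg shell and yolk, female germline, testis, accessory gland, sex determination, fat body, muscle, nerve and eye, and blood cells. Of 32 lists, that of mitochondrial genome transcripts had 0 members among the genes and was not tested. Lists were tested with camera of limma 3.58.1 at a preset correlation of 0.01, with an estimated correlation as an alternative, and with Benjamini-Hochberg adjustment over the lists of a comparison. Member counts are also given adjusted over the list alone.

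Groups, tests, lists, most alternatives and the rule for naming genes were fixed before the data were examined. The list tests and named genes of males at 4 h on 0.4% DMSO lay outside that plan. The rule took, for 0.4% against 0% DMSO at 8 h in each sex and the female slope, up to 10 genes per direction with the largest fold among those past the threshold with a mean log2 CPM of at least 0. For time and sex it took up to 8 per direction at a mean log2 CPM of at least 2. Up to 4 members per list with the smallest p, and markers of sex and clock, were added. Alternatives were RLE scaling, no expression filter, DESeq2 1.42.0, a replicate block, each library left out in turn, only the libraries of a time, dose as a number, the run as a factor or 1 run only, other foods, a minimum fold and the library with the discordant label left out. Of the alternatives, 5 were chosen after seeing the data: leaving out a library of each sex that stood apart, leaving out ribosomal RNA genes, robust empirical Bayes, egg-stage transcripts as a covariate, and 2 h as the reference time.

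The steps were tested on simulated data with 198 to 200 changed genes after filtering. For 0.4% against 0% DMSO at 8 h, 17.9% of the genes changed 2-fold and 59.1% of those changed 4-fold were recovered in females, and 48.5% and 75.8% in males. False calls were 4 among 56 in females (7.14%) and 1 among 90 in males. The simulation left out the library of each sex that stood apart. The female group on 0.4% DMSO at 8 h therefore lacked a fly and the male group did not, so these recoveries are not for equal numbers of flies. For 8 h against 0 h the 2-fold recovery was 66.7% in females and 84.8% in males, with 8 false calls among 141 in females and 10 among 172 in males.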

Results

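RNA was counted in 96 individual flies, 48 of each sex, at 4 times of refeeding and 4 levels of DMSO, with 3 flies per group. Female libraries held 2617080 to 9215800 gene counts (median 4836310) and male libraries 958896 to 8493900 (median 4744690). Transcripts that mark sex separated the libraries, with 1 exception. lncRNA:roX1, an RNA of male dosage compensation, lay between 94.9 and 515 unnormalised CPM in the male libraries, and Yp1, which encodes a yolk protein, reached at most 5.37 in them. The library labelled female, 8 h, 0.4% DMSO, replicate 3 held 134 CPM of lncRNA:roX1, 286 of the sperm-tail gene Mst84Db and 408 of the seminal-fluid gene Acp26Aa, beside 3134 of Yp1; in the other 47 female libraries lncRNA:roX1 reached at most 3.21.

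The first question was whether DMSO in the food changed transcripts at each time. After 8 h, 47 genes were higher in females on 0.4% DMSO than on food without it (3 flies against 3), and none was lower, by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment at 0.05. They included BG642312 (log2 7.91, SE 1.25, adjusted p = 0.00304), lncRNA:roX1 (log2 6.36, SE 1.30, adjusted p = 0.0156), the glycosyltransferase gene Ugt50B3 (log2 3.72, SE 0.77, adjusted p = 0.0168) and the male germline gene bol (log2 2.43, SE 0.59, adjusted p = 0.0464). All 47 were male-higher in the comparison of the sexes, and all 47 were highest in the replicate 3 library that held male transcripts. S-Lap1, a sperm leucylaminopeptidase gene, measured 0.921, 0.273 and 1133 CPM in the 3 flies, and Acp53C14b, a seminal-fluid gene, 2.46, 1.36 and 737. Both had 0 counts in the 3 controls. Without replicate 3 the count was 0.

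Among the lists, accessory gland members were higher there (camera adjusted p = 5.89e-06, 0.121 with an estimated correlation), with 1 of 4 past the threshold and 4 adjusted over the list alone. Testis members followed (2 of 7 rose, 3 adjusted over the list alone, adjusted p = 0.000738, and 0.121 with an estimated correlation). Muscle (0 of 20, adjusted p = 0.00432) and P450 genes (0 of 76, 2 adjusted over the list alone, adjusted p = 0.029) were also shifted up. Sex determination genes were shifted up too (1 of 6, 1 adjusted over the list alone, adjusted p = 0.0313), and carbohydrate digestion (adjusted p = 0.029), ribosomal proteins (0.029) and ribosome biogenesis (0.0473) down with 0 members called. For these 6 lists the adjusted p with an estimated correlation was 0.871. All of these were measured with the library that held male transcripts. In females only 4 of 38 accessory gland and 7 of 34 testis genes passed the expression filter, which depends on expression itself, so these 2 tests do not speak for the whole lists.

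**Figure D1:**
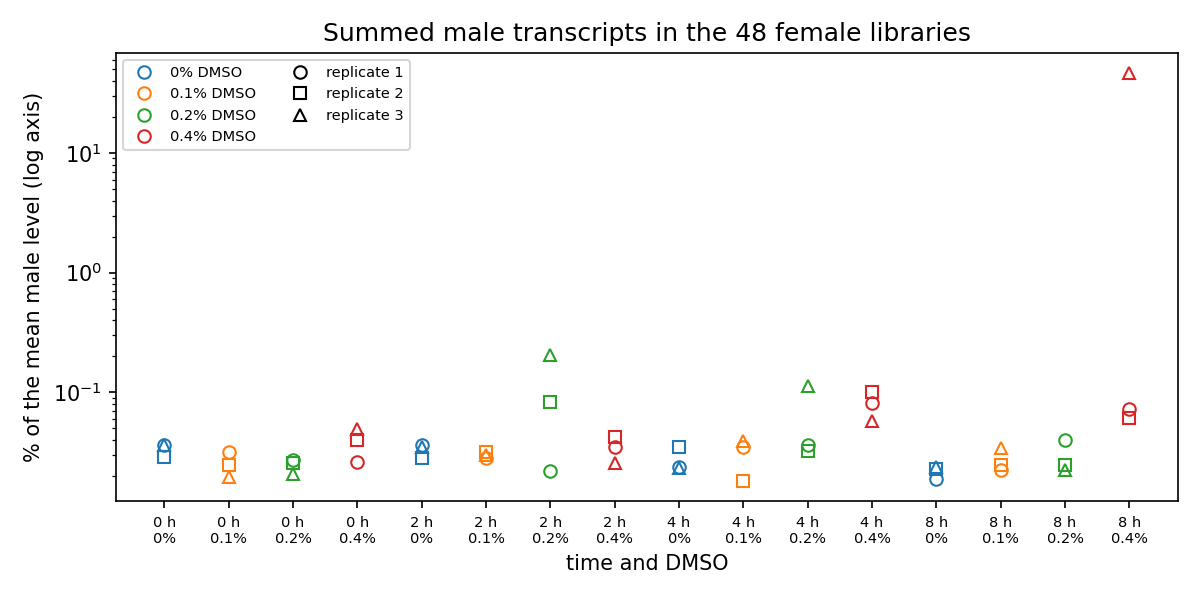
Summed level of 579 transcripts, picked as abundant in males and near 0 in the other 47 female libraries, in each of the 48 female libraries, as a percent of the mean male level on a log axis, by time and DMSO; each point is 1 fly, its colour gives the DMSO level and its shape the replicate. Replicate 3 at 8 h on 0.4% DMSO lies at 46.3%, and the highest of the others at 0.205%.

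In males after 4 h on 0.4% DMSO, 132 genes were higher than on food without it (3 flies against 3) and none lower by the same test. They included antimicrobial peptide genes of the immune response: AttC (log2 11.50, SE 2.07), DptA (log2 9.80, SE 1.72), AttB (log2 8.88, SE 1.45) and Drs (log2 6.31, SE 1.13), each with an adjusted p = 0.00359. Naming genes and testing lists for this comparison lay outside what was fixed beforehand. Of 25 immune genes tested, 17 rose (21 adjusted over the list alone, camera adjusted p = 0.0143, and 0.971 with an estimated correlation). Ribosomal protein genes rose as well, 35 of 81 (75 adjusted over the list alone, adjusted p = 7.53e-82, and 0.0586 with an estimated correlation), among them RpL36A (log2 1.25, SE 0.29). All 132 genes were highest in replicate 1: DptA measured 7061, 4.03 and 1.51 CPM in the 3 flies and Drs 13060, 37.1 and 32.04. That library was the shallowest of the series, with 958896 gene counts, of which 42.7% were ribosomal RNA. Without it the count was 0. At this time 2 of the 3 control libraries came from another sequencing run, and with the run as a factor the count was 0. The run could be estimated only from these 3 controls, which leaves little power by construction.

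**Figure D2:**
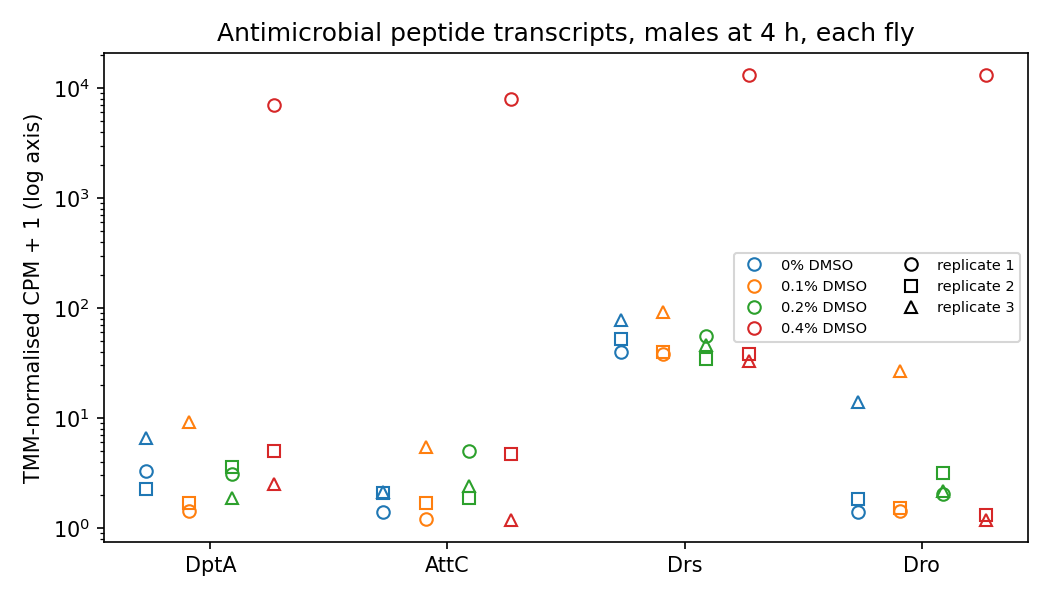
TMM-normalised CPM plus 1, on a log axis, of 4 antimicrobial peptide genes in each male at 4 h, coloured by DMSO level and shaped by replicate. The fly of replicate 1 on 0.4% DMSO lies above all 11 others for each gene, as with its DptA at 7061 CPM.

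Elsewhere the pairwise tests of a DMSO level against none (3 flies against 3) called few genes. In females, 0.1% DMSO gave 0 genes at each of 0, 2, 4 and 8 h by edgeR's quasi-likelihood test (3163, 152, 79 and 193 at an unadjusted p under 0.05, 33, 16, 11 and 6 by DESeq2). In females, 0.2% gave 0 at each time (875, 420, 735 and 83 unadjusted, 3, 11, 11 and 4 by DESeq2) and 0.4% gave 0 at 0, 2 and 4 h (314, 76 and 370 unadjusted, 2, 9 and 4 by DESeq2). In males, 0.4% gave 0 genes in edgeR at 0, 2 and 8 h (635, 644 and 628 unadjusted, 0 by DESeq2 at each). In males, 0.1% gave 0 in edgeR at 0 and 4 h (295 and 297 unadjusted, 0 by DESeq2 at both), and 0.2% gave 0 at 2 and 4 h (942 and 443 unadjusted, 13 and 0 by DESeq2). The genes named next were chosen after their values were seen. In males at 2 h on 0.1% DMSO, 3 genes of amino acid and catecholamine metabolism fell: ple, the tyrosine hydroxylase gene (log2 -1.98, SE 0.37, adjusted p = 0.0294), Gcat (log2 -2.23, SE 0.42, adjusted p = 0.0294) and AsnS, the asparagine synthetase gene (log2 -2.01, SE 0.39, adjusted p = 0.0403). There the controls and the 0.1% group came from different sequencing runs, and with the run as a factor the count was 0. Only the 4 h males without DMSO lay in both runs and could estimate that factor, so little power was left by construction. In males at 8 h, CG43235 fell on 0.1% DMSO (log2 -2.46, SE 0.41) and on 0.2% (log2 -2.12, SE 0.39), and TotX, a Turandot stress peptide gene, was higher in the 0.2% group at 0 h (log2 3.89, SE 0.64, adjusted p = 0.00645), before any DMSO food was eaten. The 0.1% count at 8 h in males went from 1 to 1242 without replicate 2 on 0.1% DMSO. With the run as a factor the calls of CG43235 on 0.2% and of TotX were lost. All males at 8 h came from 1 run, so the run cannot lie behind the CG43235 difference. The controls at 0 h all came from another run than the 0.2% group, so the TotX difference is confounded with the run.

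Tested over all 3 levels at once, DMSO gave 1 gene in females at 0 h (the ribosomal RNA pseudogene 28SrRNA-Psi:CR41609), 0 at 2 h (266 unadjusted, 3 by DESeq2), 1 at 4 h (CG16978) and 96 at 8 h. The 96 fell to 0 without the library that held male transcripts. In males the counts were 7 at 0 h, 0 at 2 h by edgeR (980 unadjusted, 70 by DESeq2), 150 at 4 h and 1 at 8 h (CG43235). The 150 fell to 0 without replicate 1 on 0.4% DMSO. The 7 genes at 0 h included the Turandot genes TotX, TotM, TotC and TotA and the immune-induced gene Diedel, before DMSO was given. A change of the DMSO effect from 0 h was called for 0 genes by edgeR in females at 2, 4 and 8 h (308, 320 and 682 unadjusted, 0, 1 and 0 by DESeq2) and in males at 2 h (849 unadjusted, 20 by DESeq2). The mean slope over feeding times in females called 1 gene, BG642312 (log2 3.99 per 0.4% DMSO, SE 0.63, adjusted p = 0.00252). At 4 h it measured 18.3, 14.0 and 13.2 CPM on 0.4% DMSO and 0.526, 2.4 and 0.461 without. Males without DMSO held 2253, 1025 and 2068. For the slope, the same 4 accessory gland genes were higher as a list (0 of 4 called, adjusted p = 3.84e-06, and 0.166 with an estimated correlation). Testis (adjusted p = 0.0351, and 0.839 with an estimated correlation), fasting and neuronal genes (0.0351) were higher and ribosomal protein and glutathione S-transferase genes (0.0369) lower with 0 called, each of these 4 at 0.983 with an estimated correlation. Without the library that held male transcripts the slope called 0 genes, so the BG642312 call rests on it. At 8 h in males the muscle list was shifted up by 0.4% DMSO (0 of 20 called, 2 adjusted over the list alone, adjusted p = 2.13e-11, and 0.437 with an estimated correlation), neuronal genes were shifted up (1.66e-06) and ribosomal proteins down (0.0149), both 0.976 with an estimated correlation. Median SEs of these contrasts were 0.37 in females at 8 h on 0.4% DMSO and 0.28 in males, and 50.7% and 66.8% of genes had a 95% interval within 1 log2 unit of 0.

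The next question was how transcripts changed when starved flies were refed. In females after 2 h, 933 genes rose and 440 fell against 0 h (12 flies against 12, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). This count of 1373 ran from 790 to 2227 when 1 library was left out, and was 3 on food without DMSO alone (3 flies against 3). Genes of fasting fell, among them the lipase gene bmm (log2 -1.05, SE 0.15, adjusted p = 0.000133), which went from 122 ± 46.2 to 58.2 ± 14.8 CPM (SD, n = 12), and Lip3, another lipase gene (log2 -4.06, SE 0.85, adjusted p = 0.00557). Of 22 fasting genes 5 fell, 7 adjusted over the list alone (camera adjusted p = 5.75e-05). Carbohydrate digestion fell in 7 of 14 (10 adjusted over the list alone, adjusted p = 4.53e-05), with the amylase-related gene Amyrel (log2 -4.90, SE 0.90, adjusted p = 0.00204) and the maltase genes Mal-A3 (log2 -4.08, SE 0.85) and Mal-A4 (log2 -3.56, SE 0.80). Neuronal and eye genes rose in 11 of 21 (15 adjusted over the list alone, adjusted p = 4.84e-07), among them the synaptic gene brp (log2 1.16, SE 0.26) and elav, an RNA-binding protein gene of neurons (log2 1.05, SE 0.25). Muscle genes rose in 8 of 20 (19 adjusted over the list alone, adjusted p = 3.19e-06), with fln (log2 2.06, SE 0.59) and Act88F (log2 1.83, SE 0.58), both of flight muscle. With an estimated correlation the adjusted p of each of these lists was 0.834.

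Genes that rose at 2 h in females included the lysozyme gene LysE (log2 3.32, SE 0.80), the larval serum protein gene Lsp1beta (log2 2.73, SE 0.70, but -0.32 on food without DMSO), the Jonah protease gene Jon25Bii (log2 2.62, SE 0.78), the cuticle gene Cpr47Ea (log2 2.18, SE 0.53) and CG3348 (log2 2.23, SE 0.31). Genes that fell included CG6277 (log2 -6.53, SE 1.10), the lysosomal mannosidase genes LManVI (log2 -6.27, SE 1.47) and LManV (log2 -5.75, SE 1.35), yellow-g2 of the egg shell (log2 -5.97, SE 2.02) and the antimicrobial peptide gene Dro (log2 -5.35, SE 1.26). Of 29 immune genes 9 fell and 1 rose (12 and 2 adjusted over the list alone), and the list did not pass (adjusted p = 0.283). Dro and DptA were high in few flies at 0 h: replicate 1 without DMSO held 3792 unnormalised CPM of Dro and 4429 of DptA, and without that library the Dro call was lost. Ribosomal proteins fell in 5 of 78 (2 adjusted over the list alone, adjusted p = 2.57e-05). Digestive proteases rose in 1 and fell in 4 of 28 (1 and 4 adjusted over the list alone, adjusted p = 0.0213). Of the clock list 2 of 12 rose (5 adjusted over the list alone, camera adjusted p = 0.0155), sr and Clk (log2 0.66, SE 0.20). The sr gene also stands in the neuronal activity list. Female germline genes were lower as a list with 0 of 26 called (adjusted p = 0.0426); with an estimated correlation the adjusted p of these 4 lists was 0.834. Of the clock checks, per (log2 0.65, adjusted p = 0.0735) and tim (log2 0.43, adjusted p = 0.196) did not pass.

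**Figure D3:**
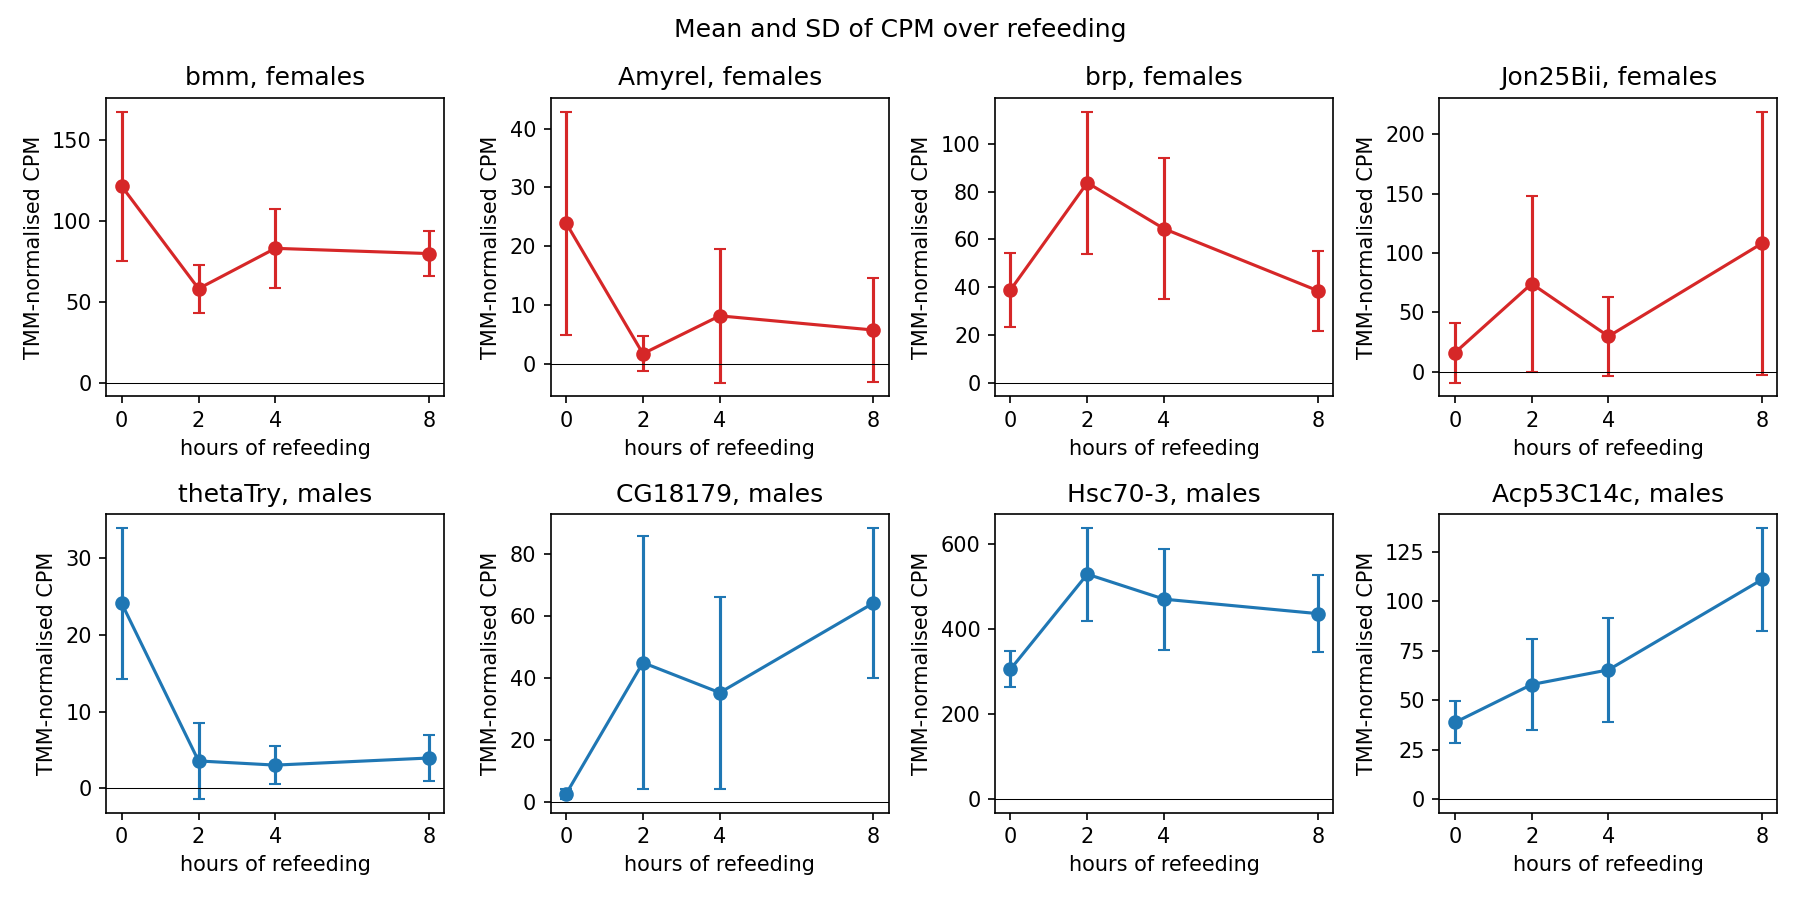
TMM-normalised CPM against hours of refeeding, as mean and SD, for 4 genes in females (12 flies per time, red) and 4 in males (9 flies per time, blue). In females bmm lies at 122 at 0 h and 58.2 at 2 h, and in males Acp53C14c lies at 38.7 at 0 h and 111 at 8 h.

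At 4 h in females 0 genes passed in edgeR (1615 unadjusted, 255 by DESeq2), while 11 lists did. With only the 3 foods with DMSO 232 genes passed, and with 1 library left out up to 117. Neuronal and eye genes (adjusted p = 1.59e-07, 12 adjusted over the list alone), muscle (0.000746), neuronal activity (0.013, 2 adjusted over the list alone), clock (0.0166, 1 adjusted over the list alone) and nutrient hormone genes (0.0167, 2 adjusted over the list alone) were higher. Fasting genes (0.000248, 2 adjusted over the list alone), ribosome biogenesis (0.00073), egg shell (0.000837, 5 adjusted over the list alone), female germline (0.00126), carbohydrate digestion (0.0016) and digestive proteases (0.0081) were lower. With an estimated correlation the adjusted p of each of the 11 was 0.711. At 8 h, 50 genes rose and 311 fell. This count of 361 went to 28 without the 0 h fly with high antimicrobial peptides (replicate 1 without DMSO), and to 4 with only the 3 foods with DMSO. Of the 933 genes that rose at 2 h, 5 also rose at 8 h, where independent lists give 4.637. Of the 440 that fell at 2 h, 95 also fell at 8 h, where independent lists give 13.6. Both times were set against the same 0 h flies, which raises the overlap. Ribosomal protein genes were among the falls: 44 of 78 fell (65 adjusted over the list alone, adjusted p = 1.43e-38, and 0.487 with an estimated correlation), with RpL10Ab (log2 -0.61, SE 0.12, adjusted p = 0.0127) and RpL39 (log2 -0.59, SE 0.12). Fasting genes fell in 3 of 22 (8 adjusted over the list alone, adjusted p = 8.41e-05, and 0.487 with an estimated correlation): the adipokinetic hormone receptor gene AkhR (log2 -1.43, SE 0.35), bmm (log2 -0.58, SE 0.15) and Lip4 (log2 -1.24). Fat synthesis fell in 2 of 20 (5 adjusted over the list alone, adjusted p = 8.41e-05, and 0.554 with an estimated correlation), Desat1 (log2 -0.73) and Acsl (log2 -0.50). Ribosome biogenesis fell in 6 of 26 (8 adjusted over the list alone, adjusted p = 0.00098, and 0.705 with an estimated correlation). Fat body genes fell in 4 of 13 (6 down and 1 up adjusted over the list alone, adjusted p = 0.0279, and 0.705 with an estimated correlation). Jon25Bii (log2 3.00, SE 0.79) and the chitinase gene Cht8 (log2 1.08, SE 0.29) rose, and the chorion gene Cp16 (log2 -4.82, SE 1.33) and the mucin gene Muc4B (log2 -4.79, SE 1.19) fell. BG642312 (log2 2.48, but -0.18 on food without DMSO) and CG4546 (log2 2.56), both male-higher genes, rose among libraries that include the one with male transcripts.

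Among the other female lists at 8 h, P450 genes rose in 2 and fell in 4 of 76 (4 and 12 adjusted over the list alone, adjusted p = 0.000907, and 0.87 with an estimated correlation). Cyp4d21 (log2 1.28, SE 0.37), a male-higher gene, was among those that rose, and these libraries include the one with male transcripts. Glycosyltransferases fell in 2 of 29 (5 adjusted over the list alone, adjusted p = 0.00197, and 0.799 with an estimated correlation). Sugar response fell in 1 of 10, Lst (4 adjusted over the list alone, adjusted p = 0.0309, and 0.705 with an estimated correlation). Blood cell genes were lower with 0 of 12 called (3 adjusted over the list alone, adjusted p = 0.00722, and 0.705 with an estimated correlation). Immune genes fell in 4 of 29 (13 down and 1 up adjusted over the list alone, adjusted p = 0.0694), among them BomS1 (log2 -3.31, SE 0.75, adjusted p = 0.018), a gene of a secreted immune peptide. Egg shell genes fell in 3 of 25 (9 adjusted over the list alone, adjusted p = 0.114). Neuronal and eye genes were lower with 0 of 21 called (0 adjusted over the list alone, adjusted p = 0.0309, and 0.87 with an estimated correlation).

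In males after 2 h, 80 genes rose and 97 fell (9 flies against 9, same test). This count of 177 ran from 94 to 261 when 1 library was left out, and was 22 on food without DMSO alone. CG18179, of the serine protease family, rose (log2 3.74, SE 0.60, adjusted p = 0.00104), from 2.50 ± 1.63 to 44.8 ± 40.9 CPM (SD, n = 9), and the trypsin gene thetaTry fell (log2 -3.50, SE 0.50, adjusted p = 0.00038), from 24.1 ± 9.86 to 3.55 ± 4.97. Fasting genes fell in 4 of 21 (9 adjusted over the list alone, adjusted p = 6.2e-09, and 0.127 with an estimated correlation): foxo, the transcription factor gene of fasting (log2 -0.60, SE 0.14), REPTOR-BP (log2 -0.73), whd (log2 -0.68) and Pepck2 (log2 -1.07, but 0.27 on food without DMSO). Chaperone genes of the endoplasmic reticulum rose in 3 of 15 of the unfolded protein response (4 adjusted over the list alone, adjusted p = 0.015, and 0.277 with an estimated correlation): Hsc70-3 (log2 0.78, SE 0.13), Gp93 (log2 0.79, SE 0.14) and Calr (log2 0.54, SE 0.12). Hr38, a nuclear receptor gene induced by neuronal activity (log2 1.16, SE 0.23), also rose, the 1 of 8 members of its list (2 adjusted over the list alone, adjusted p = 0.0146, and 0.422 with an estimated correlation). Neuronal and eye genes (adjusted p = 5.41e-06, and 0.534 with an estimated correlation), clock genes (0.0146, and 0.277 with an estimated correlation) and accessory gland genes (0.0105, and 0.643 with an estimated correlation) were higher and testis genes lower (0.0155, and 0.643 with an estimated correlation) with 0 members called. Digestive proteases fell in 2 of 25 (3 adjusted over the list alone, adjusted p = 2.91e-08, and 0.167 with an estimated correlation). P450 genes fell in 5 of 74 (7 adjusted over the list alone, adjusted p = 2.82e-05, and 0.299 with an estimated correlation). Carbohydrate digestion fell in 1 of 14, Mal-A7 (7 adjusted over the list alone, adjusted p = 3.08e-07, and 0.167 with an estimated correlation).

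At 4 h in males 64 genes rose and 57 fell. This count of 121 ran from 30 to 346 when 1 library was left out, and was 68 without the library with 2 time labels, 0 on food without DMSO alone and 344 with all 4 foods. Fasting genes fell in 5 of 21 (6 adjusted over the list alone, adjusted p = 4.65e-12, and 0.0394 with an estimated correlation), with Pepck2, of gluconeogenesis (log2 -1.55, SE 0.31, adjusted p = 0.00806), and foxo (log2 -0.67, SE 0.14). It was the only list of the time comparisons against 0 h that passed with an estimated correlation. CG18179 (log2 3.91, SE 0.61), the peptidoglycan recognition gene PGRP-SB1 (log2 2.67, SE 0.69) and the metallothionein gene MtnD (log2 2.17, SE 0.55) rose; thetaTry (log2 -3.13, SE 0.50) and the cuticle gene Cpr67Fb (log2 -2.29, SE 0.43) fell. The 4 h libraries include the male fly with high antimicrobial peptides, and without it 3 immune genes fell and 0 rose. Fat synthesis fell in 2 of 20 (2 adjusted over the list alone, adjusted p = 0.00117, and 0.412 with an estimated correlation), among them the lipid droplet gene Lsd-2 (log2 -0.50). Turandot genes fell in 1 of 4 (4 adjusted over the list alone, adjusted p = 0.011, and 0.496 with an estimated correlation). JNK and JAK-STAT genes were lower with 0 of 7 called (2 adjusted over the list alone, adjusted p = 0.0245, and 0.381 with an estimated correlation). Digestive proteases fell in 1 of 25 (3 adjusted over the list alone, adjusted p = 2.19e-06, and 0.381 with an estimated correlation). P450 genes fell in 2 of 74 (6 down and 2 up adjusted over the list alone, adjusted p = 0.00266, and 0.52 with an estimated correlation). Carbohydrate digestion (adjusted p = 0.000371, and 0.397 with an estimated correlation), sugar response (0.00554, and 0.358 with an estimated correlation) and muscle (0.04, and 0.798 with an estimated correlation) were lower, and ribosomal protein (8.88e-07) and accessory gland genes (0.00554) higher, both 0.798 with an estimated correlation, with 0 members called. Heat shock rose in 1 of 11 (1 adjusted over the list alone, adjusted p = 0.0963).

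At 8 h in males 879 genes rose and 554 fell. This count of 1433 ran from 864 to 1970 when 1 library was left out, and was 4 on food without DMSO alone. On that food the 8 h and 0 h males came from different sequencing runs, so that count and the folds on it below are confounded with the run. Seminal-fluid genes of the accessory gland rose together, 25 of 38 (30 up and 2 down adjusted over the list alone, adjusted p = 2.75e-19, and 0.415 with an estimated correlation). Acp53C14c (log2 1.52, SE 0.21, adjusted p = 3.38e-05) went from 38.7 ± 10.6 to 111 ± 26.1 CPM (SD, n = 9), and Acp53C14b (log2 1.08, SE 0.16) and Acp33A (log2 1.12, SE 0.17) rose as well. Glutathione S-transferase genes of detoxification rose in 10 of 33 (14 adjusted over the list alone, adjusted p = 0.000181, and 0.415 with an estimated correlation), with GstE7 (log2 1.02, SE 0.25) and GstE6 (log2 0.68, SE 0.15). Ribosome biogenesis fell in 5 of 26 (7 adjusted over the list alone, adjusted p = 1.26e-06, and 0.415 with an estimated correlation), including Ns2 (log2 -0.37, but 0.04 on food without DMSO) and mbm (log2 -0.59). Fasting genes fell in 3 of 21 (5 adjusted over the list alone, adjusted p = 0.000181, and 0.415 with an estimated correlation), including AkhR (log2 -0.95, but 0.32 on food without DMSO) and bmm (log2 -0.62). Turandot stress peptides fell in 3 of 4: TotC (log2 -5.05, SE 0.85), TotM (log2 -4.19, SE 0.85) and TotA (log2 -3.37, SE 0.69); their list did not pass (adjusted p = 0.193, 3 adjusted over the list alone). TotC was uneven at 0 h, at 329 ± 638 CPM, against 2.54 ± 2.66 at 8 h (SD, n = 9). Jon25Bii (log2 3.77, SE 0.87), Jon25Bi (log2 2.70, SE 0.76) and the larval serum protein gene Lsp2 (log2 2.73, SE 0.78) rose, as did the insulin-like peptide gene Ilp2 (log2 0.98, SE 0.22, adjusted p = 0.00283).

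Members of other male lists changed at 8 h in lists that did not pass. Genes of the unfolded protein response rose in 4 of 15 (5 up and 1 down adjusted over the list alone, adjusted p = 0.434). Oxidative stress rose in 3 and fell in 1 of 20 (4 and 1 adjusted over the list alone, adjusted p = 0.193), with the superoxide dismutase genes Sod3 (log2 0.37) and Sod2 (log2 0.24). Sulfur and methionine genes rose in 3 of 12 (3 adjusted over the list alone, adjusted p = 0.493): b (log2 0.89), MsrA (log2 0.46) and SelR (log2 0.30, but -0.15 on food without DMSO). That last fold is confounded with the sequencing run. Nutrient hormones rose in 2 of 19 (2 adjusted over the list alone, adjusted p = 0.223). Glycolysis fell in 1 of 13 (1 adjusted over the list alone, list adjusted p = 0.639), the hexokinase gene Hex-C (log2 -0.55), and cell death changed in 0 of 7 (0 adjusted over the list alone, adjusted p = 0.931). Fat synthesis fell in 5 of 20 (5 adjusted over the list alone) and passed as a list (adjusted p = 0.0379, and 0.783 with an estimated correlation), with FASN2, a fatty acid synthase gene (log2 -1.07).

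The sexes were compared on food without DMSO (6 flies against 6, mean over 0 and 2 h). They differed in 7949 genes by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 3144 higher in females and 4805 in males, and 5051 of them by at least 1 log2 unit. In females the yolk protein gene Yp1 (log2 11.82, SE 0.62, adjusted p = 7.14e-10) and osk, which sets up the germ plasm (log2 10.73, SE 0.39), were higher. Vm26Ab, of the vitelline membrane, had 0 counts in the males, at least 3000-fold lower than in females against a floor of 3 counts over the group. The seminal-fluid genes Ebp (at least 63700-fold) and Acp36DE (at least 21700-fold), and loopin-1 (at least 20400-fold) and S-Lap7 (at least 21000-fold) of the sperm, had 0 counts in the females against the same floor. Ribosome biogenesis genes were female-higher in 26 of 26 (26 adjusted over the list alone, adjusted p = 2.75e-11, and 0.458 with an estimated correlation), with Nop60B (log2 3.02, SE 0.23). Ribosomal proteins were female-higher in 76 of 81 (76 adjusted over the list alone, adjusted p = 7.87e-20, and 0.505 with an estimated correlation). The 4 male-higher ribosomal protein genes included the paralogs RpS19b (log2 -5.52, SE 0.24) and RpS10a (log2 -8.77, SE 0.47). Testis genes were male-higher in 33 of 34 and accessory gland genes in 37 of 37 (33 and 37 adjusted over the list alone, adjusted p = 4.37e-13 and 8.62e-16, and 0.458 with an estimated correlation for both). Egg shell and yolk genes were female-higher in 20 of 21 and female germline genes in 22 of 26 with 2 male-higher (20, 22 and 2 adjusted over the list alone, adjusted p = 7.6e-06 and 1.22e-08, and 0.458 with an estimated correlation for both). Carbohydrate digestion was female-higher in 7 of 14 (7 adjusted over the list alone, adjusted p = 0.0375). Fasting genes were female-higher in 7 of 22 with 1 male-higher (7 and 1 adjusted over the list alone, adjusted p = 0.0375) and digestive proteases in 5 of 27 (4 adjusted over the list alone, adjusted p = 0.0153). For these 3 lists the adjusted p with an estimated correlation was 0.87. Of the sex-determination checks, Sxl was female-higher (log2 0.97, SE 0.13) and msl-2 (log2 -1.18, SE 0.18) and lncRNA:roX1 (log2 -8.17, SE 0.31) male-higher.

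The last comparison asked whether the sexes differed in their change over refeeding (all 96 libraries, foods with DMSO). The change from 0 h differed in 1 gene at 2 h, CG11854 (log2 4.27 female minus male, SE 0.82, adjusted p = 0.0284), in 0 at 4 h (1496 unadjusted, 395 by DESeq2) and in 6 at 8 h by edgeR's quasi-likelihood test. DESeq2 gave 535 at 2 h and 709 at 8 h, and with 1 library left out edgeR gave 0 to 194 and 0 to 127. Of the 6, chosen after their values were seen, CG7768 (log2 3.06, SE 0.58) had the smallest p and CG14223 (log2 -1.07, SE 0.23) was the 1 with a lower change in females. CG7768 and CG4546, also among the 6, were male-higher in the comparison of the sexes. They held 1.07 and 0.644 CPM in females and 327 and 613 in males. Without the female library that held male transcripts the count at 8 h was 0, so the 6 calls depend on it. Without the libraries that stood apart the counts at 2, 4 and 8 h were 20, 1 and 0. The DMSO effect at 8 h differed between the sexes in 2313 genes, and in 5 without those libraries.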

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

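The patterns weighed here were chosen after the data were seen. The criteria for the splits of libraries, for the share of male RNA and for the handling of the 0 h flies were written after their values were seen, and those of the other tests before. Results were set apart because the sexes differed in their response by a test of the difference itself. The change from 0 h differed between the sexes in 1 gene at 2 h and 6 genes at 8 h, and the DMSO effect at 8 h in 2313 genes. Among splits of the same libraries, 21 of 60 gave as many genes as the 2313 (highest other 2470), so the splits did not exclude chance. Each split keeps, at 8 h, the female library that held male transcripts. Without that library the count was 4, so the 2313 rest on it. For the change from 0 h, chance could not be excluded at 2 h (10 of 60 reached 1, highest other 24) or at 8 h (3 of 60 reached 6, highest other 135). The 6 at 8 h also fell to 0 without the female library that held male transcripts. At 4 h the count was 0, which all 60 of 60 splits reach by construction (highest other 55), so nothing was tested. Spike-in transcripts, which no comparison used, were set apart as a signal outside the genes. At 0 h they took a median of 2.68% of gene and spike-in counts in females and 4.13% in males, against 0.367% and 0.360% at later times.

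The 47 genes higher in females on 0.4% DMSO at 8 h were weighed first. Male RNA in 1 library of the group fitted: 579 transcripts, picked as abundant in males and near 0 in the other 47 female libraries, lay at a median of 41.64% of the male level in replicate 3 (quartiles 34.41 and 50.85%). Their low level in the other females follows from that choice. RNA of the male in the adjacent well was ruled out, as that male ranked 20 of 48 by correlation (r = 0.154). The male on 0.1% DMSO in the same plate column was picked because it ranked first (r = 0.945), and it ranked 1 again on 924 other transcripts (r = 0.757, next 0.687). DMSO feeding as the whole cause was ruled out, since both other flies lay above all controls in 10 of the 47 genes, under the bound of 11.75. That is above the 10% that chance gives. The genes were picked by a contrast that includes these flies, which raises the share, so a part played by DMSO was not decided.

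The 132 genes higher in males on 0.4% DMSO at 4 h were weighed next. DMSO feeding as the whole cause was ruled out, with both other flies above all controls in 25 of the genes against a bound of 33. That too is above the 10% that chance gives, for genes picked by a contrast that includes these flies, so a part played by DMSO was not decided. A difference in depth between libraries was ruled out as the whole cause, as 114 of the genes were still called with all male libraries thinned to 958896 counts. The shallow library kept its own counts there, so its quality and composition (42.7% ribosomal RNA) were not tested. Leaving out ribosomal RNA genes lowered the count, as given below. The sequencing run was ruled out as the whole cause: at 0 h, between the same runs, the genes differed by a median log2 of 0.1345 (quartiles 0.01 and 0.59), against 2.37 at 4 h. The state of that single fly, such as an infection, could raise antimicrobial peptides, and no test here (25, 114 and 0.1345) decides it.

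The genes that changed over feeding time were weighed last, against a different handling of the 0 h flies or their RNA. All 12 libraries at 0 h had a spike-in share above every 2 h library, in females (12) and in males (12). The lowest share at 0 h was 1.75% in females and 1.91% in males, against at most 0.618% and 1.14% at 2, 4 and 8 h. For any change from 0 h, refeeding thus cannot be told from handling. Single spike-ins also differed between 0 h and later times (28 of 42 called in females and 34 of 39 in males), and between 8 and 2 h 0 of 42 in females and 8 of 39 in males. Per the labels the 2 pools were assigned by DMSO, but 0 were called between foods with DMSO and without. Which pool each library received stays open, and the share is no clean sign of handling. Between 2 and 8 h, 2994 genes were called in females (highest other split 4246) and 536 in males (highest other 34). No 0 h library enters that comparison, so these counts say nothing on the handling of the 0 h flies.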

How the results depend on the processing

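The count of the sex comparison stayed within 1.5 times under every alternative but a minimum change, with 7547 to 8262 genes when a library was left out. Below, a DMSO level alone means that level against none, and a time alone means against 0 h. Results below are counts of genes past the threshold that moved by over 1.5 times, and named genes that changed sign. The cause was not tested, except that leaving out flies or fitting fewer libraries lowers the power by construction. So does the run as a factor, which only the 4 h males without DMSO, the only group in both runs, can estimate. Other counts stayed within 1.5 times of the value given. In the fit of both sexes, leaving out a library kept the dispersion trend of the full fit. RLE scaling moved the share of rising genes among calls by at most 4.45 points, DESeq2, which also changes the test, by at most 8.59 points, and RLE moved the median gene by at most 0.07 log2 units. Simulated data for 0.4% DMSO at 8 h in females recovered 17.9% of 2-fold and 59.1% of 4-fold changes. They were made without the female library that held male transcripts, so that group had a fly fewer than in the real comparison. Replicate numbers did not pair: 0 of 24 contrasts had all 3 correlations above 0.1.

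With RLE scaling, counts became DMSO levels, females, 4 h 2 (from 1). With no low-count filter, counts became DMSO levels, females, 4 h 2 (from 1), DMSO levels, females, 8 h 783 (from 96), 0.4%, females, 8 h 194 (from 47), 4 h, females 2 (from 0). Also 0.2%, males, 0 h 2 (from 1). With DESeq2, counts became DMSO levels, females, 0 h 18 (from 1), 0.1%, females, 0 h 33 (from 0), 0.2%, females, 0 h 3 (from 0), 0.4%, females, 0 h 2 (from 0). Also DMSO levels, females, 2 h 3 (from 0), 0.1%, females, 2 h 16 (from 0), 0.2%, females, 2 h 11 (from 0), 0.4%, females, 2 h 9 (from 0). Also DMSO levels, females, 4 h 43 (from 1), 0.1%, females, 4 h 11 (from 0), 0.2%, females, 4 h 11 (from 0), 0.4%, females, 4 h 4 (from 0). Also 0.1%, females, 8 h 6 (from 0), 0.2%, females, 8 h 4 (from 0), 0.4%, females, 8 h 94 (from 47), DMSO slope, females 4 (from 1). Also changed DMSO effect, females, 4 h 1 (from 0), 4 h, females 255 (from 0), 8 h, females 704 (from 361), 0.2%, males, 0 h 4 (from 1). Also DMSO levels, males, 2 h 70 (from 0), 0.1%, males, 2 h 33 (from 3), 0.2%, males, 2 h 13 (from 0), DMSO levels, males, 4 h 300 (from 150). Also 0.4%, males, 4 h 264 (from 132), DMSO levels, males, 8 h 13 (from 1), 0.1%, males, 8 h 29 (from 1), changed DMSO effect, males, 2 h 20 (from 0). Also 2 h, males 290 (from 177), 4 h, males 246 (from 121), sex by time, 2 h 535 (from 1), sex by time, 4 h 395 (from 0). Also sex by time, 8 h 709 (from 6). With the replicate number as a block (replicate block), counts became DMSO levels, females, 0 h 0 (from 1), DMSO levels, females, 4 h 0 (from 1), DMSO levels, females, 8 h 53 (from 96), 0.4%, females, 8 h 17 (from 47). Also 0.1%, males, 2 h 0 (from 3), DMSO levels, males, 4 h 59 (from 150), 0.4%, males, 4 h 42 (from 132), 0.2%, males, 8 h 0 (from 1). Also sex by time, 8 h 2 (from 6). Without the 2 libraries that stood apart (chosen after seeing the data), counts became DMSO levels, females, 8 h 0 (from 96), 0.4%, females, 8 h 0 (from 47), DMSO slope, females 0 (from 1), 8 h, females 562 (from 361). Also 0.2%, males, 0 h 3 (from 1), DMSO levels, males, 2 h 7 (from 0), DMSO levels, males, 4 h 0 (from 150), 0.4%, males, 4 h 0 (from 132). Also DMSO levels, males, 8 h 2 (from 1), 0.1%, males, 8 h 2 (from 1), 2 h, males 325 (from 177), 4 h, males 191 (from 121). Also sex by time, 2 h 20 (from 1), sex by time, 4 h 1 (from 0), sex by time, 8 h 0 (from 6), sex by DMSO, 8 h 5 (from 2313). Without ribosomal RNA genes (chosen after seeing the data), counts became DMSO levels, females, 0 h 0 (from 1), DMSO levels, females, 4 h 2 (from 1), 4 h, females 1 (from 0), 0.4%, males, 4 h 79 (from 132). With only the libraries of a time fitted, counts became DMSO levels, females, 0 h 0 (from 1), 0.1%, females, 0 h 26 (from 0), DMSO levels, females, 4 h 0 (from 1), DMSO levels, females, 8 h 0 (from 96). Also 0.4%, females, 8 h 0 (from 47), DMSO levels, males, 0 h 0 (from 7), 0.2%, males, 0 h 0 (from 1), DMSO levels, males, 2 h 11 (from 0). Also 0.1%, males, 2 h 0 (from 3), 0.2%, males, 2 h 1 (from 0), DMSO levels, males, 4 h 0 (from 150), 0.4%, males, 4 h 0 (from 132). Also DMSO levels, males, 8 h 0 (from 1), 0.1%, males, 8 h 0 (from 1), 0.2%, males, 8 h 0 (from 1). With dose as a number, counts became DMSO levels, females, 4 h 0 (from 1), DMSO levels, males, 0 h 0 (from 7), DMSO levels, males, 8 h 0 (from 1). On food without DMSO alone (3 flies against 3), counts became 2 h, females 3 (from 1373), 8 h, females 1 (from 361), 2 h, males 22 (from 177), 4 h, males 0 (from 121). Also 8 h, males 4 (from 1433), a comparison confounded with the sequencing run. With only the 3 foods with DMSO in females, counts became 4 h, females 232 (from 0), 8 h, females 4 (from 361). Against 2 h instead of 0 h (chosen after seeing the data), counts became 8 h, females 2994 (from 361), 4 h, males 0 (from 121), 8 h, males 536 (from 1433). With egg-stage transcripts as a covariate (chosen after seeing the data), counts became DMSO levels, females, 4 h 0 (from 1), 4 h, females 1 (from 0). With robust empirical Bayes (chosen after seeing the data), counts became 0.1%, males, 8 h 2 (from 1). With all 4 foods in males, counts became 2 h, males 493 (from 177), 4 h, males 344 (from 121). With the sequencing run as a factor, counts became 0.2%, males, 0 h 0 (from 1), 0.1%, males, 2 h 0 (from 3), DMSO levels, males, 4 h 74 (from 150), 0.4%, males, 4 h 0 (from 132). Also 0.2%, males, 8 h 0 (from 1). With only the second run, counts became DMSO levels, males, 4 h 46 (from 150), 0.4%, males, 4 h 0 (from 132). Without the library with 2 time labels, counts became 0.2%, males, 0 h 4 (from 1), 0.2%, males, 8 h 0 (from 1), 4 h, males 68 (from 121). With a minimum change of 1 log2 unit, counts became 2 h, females 555 (from 1373), 8 h, females 177 (from 361), 2 h, males 60 (from 177), 4 h, males 37 (from 121). Also 8 h, males 255 (from 1433), sex 5051 (from 7949).

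With an estimated correlation, the number of passing lists became 0.4%, females, 8 h 0 (from 8), 0.4%, males, 8 h 0 (from 3), DMSO slope, females 0 (from 6), 2 h, females 0 (from 8). Also 4 h, females 0 (from 11), 8 h, females 0 (from 10), 2 h, males 0 (from 10), 4 h, males 1 (from 11). Also 8 h, males 0 (from 5), sex 0 (from 9). With fry, the number of passing lists became 0.4%, females, 8 h 0 (from 8), 0.4%, males, 8 h 0 (from 3), DMSO slope, females 0 (from 6), 2 h, females 3 (from 8). Also 4 h, females 0 (from 11), 8 h, females 2 (from 10), 2 h, males 6 (from 10), 4 h, males 1 (from 11). Without the 2 libraries that stood apart (chosen after seeing the data), the number of passing lists became 0.4%, females, 8 h 4 (from 8).

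Leaving out each library in turn gave DMSO levels, females, 0 h 0 to 29, 0.1%, females, 0 h 0 to 7, 0.4%, females, 0 h 0 to 1, changed DMSO effect, females, 8 h 0 to 20. It gave 2 h, females 790 to 2227, 4 h, females 0 to 117, 8 h, females 28 to 562, DMSO levels, females, 8 h 0 to 148. It gave 0.4%, females, 8 h 0 to 145, DMSO slope, females 0 to 12, DMSO levels, females, 2 h 0 to 1, DMSO levels, females, 4 h 0 to 29. It gave 0.2%, females, 4 h 0 to 2, DMSO levels, males, 0 h 5 to 11, 0.1%, males, 0 h 0 to 1, 0.2%, males, 0 h 0 to 10. It gave 0.4%, males, 0 h 0 to 1, changed DMSO effect, males, 2 h 0 to 10, DMSO levels, males, 8 h 0 to 367, 0.1%, males, 8 h 0 to 1242. It gave 0.2%, males, 8 h 0 to 1, 0.4%, males, 8 h 0 to 2, DMSO levels, males, 2 h 0 to 13, 0.1%, males, 2 h 0 to 5. It gave 0.2%, males, 2 h 0 to 3, DMSO levels, males, 4 h 0 to 387, 0.4%, males, 4 h 0 to 448, 2 h, males 94 to 261. It gave 4 h, males 30 to 346, 8 h, males 864 to 1970, sex by DMSO, 8 h 4 to 2521, sex by time, 2 h 0 to 194. It gave sex by time, 4 h 0 to 4, sex by time, 8 h 0 to 127. Leaving out a library moved Ugt50B3, 0.4%, females, 8 h over log2 -0.36 to 4.225. Leaving out a library moved lncRNA:roX1, 0.4%, females, 8 h over log2 -0.37 to 6.89. Leaving out a library moved Drs, 0.4%, males, 4 h over log2 -0.66 to 6.899.

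Without the 2 libraries that stood apart, the log2 fold of named genes turned to Ugt50B3, 0.4%, females, 8 h -0.36, lncRNA:roX1, 0.4%, females, 8 h -0.37, Drs, 0.4%, males, 4 h -0.66. On food without DMSO alone, the log2 fold of named genes turned to Lsp1beta, 2 h, females -0.32, BG642312, 8 h, females -0.18, Pepck2, 2 h, males 0.27, AkhR, 8 h, males 0.32. Also Ns2, 8 h, males 0.04216, SelR, 8 h, males -0.15. On that food the males at 8 h are confounded with the sequencing run. Against 2 h, the log2 fold of named genes turned to bmm, 8 h, females 0.47, Lst, 8 h, females 0.15, CG3348, 4 h, males -0.31, CG6277, 4 h, males 1.60. Also thetaTry, 4 h, males 0.37, Gp93, 4 h, males -0.07495, Hsc70-3, 4 h, males -0.16, Calr, 4 h, males -0.07059. Also CG6277, 8 h, males 1.38, bmm, 8 h, males 0.004395, thetaTry, 8 h, males 0.92, Gp93, 8 h, males -0.15. Also Hsc70-3, 8 h, males -0.27, Calr, 8 h, males -0.11. On food without DMSO at 8 h, the log2 fold of named genes turned to Lst, sex -0.83, Mal-A7, sex -0.53.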

Other observations

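In females on 0.4% DMSO, 2 transcripts of the male reproductive tract were above the controls at 4 h in all 3 flies, away from the library with male RNA; they were singled out after their values were seen. Acp53C14b, a seminal-fluid gene, measured 5.03, 6.27 and 3.01 CPM against 0, 0 and 0, and BG642312 measured 18.3, 14.0 and 13.2 CPM against 0.526, 2.4 and 0.461. Males without DMSO at 0 and 2 h held means of 703 and 1354 CPM of these genes. The summed share of the 579 male transcripts in the 3 females was 0.0806, 0.1 and 0.057%, so both genes lay above that share of the male level.

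This pattern was noticed in the data, and the criterion was written before its test was run. Females on 0.4% DMSO shared a plate border with the first male row, so carry-over between neighbouring rows may lie behind the trace male transcripts. Median trace male shares were 0.0284, 0.0289, 0.0295 and 0.0493% in the 4 female rows. The highest single shares did not follow the border. They were 0.205% (2 h, replicate 3) and 0.113% (4 h, replicate 3) on 0.2% DMSO, in a row away from the males. On 0.4% DMSO the highest was 0.1%, leaving out the library with male RNA. Among males at 8 h, 26 female transcripts in the bordering row lay at 0.0671% against 0.0443% in the other rows as means (exact one-sided p = 0.0636, 220 splits), which decides nothing. By medians the bordering row was not the highest (0.0525% against 0.0545, 0.039 and 0.0441%), and 1 library at 0.0992% raised its mean.

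The antimicrobial peptide gene DptA was high in few single flies. It exceeded 100 unnormalised CPM in female 0 h without DMSO replicate 1 (4429), female 0 h on 0.2% replicate 3 (1096), female 8 h on 0.1% replicate 3 (172), female 8 h on 0.2% replicate 3 (105) and male 4 h on 0.4% replicate 1 (3865). Female 4 h on 0.2% replicate 3 had 61.4 of DptA but 4688 of Drs and 1829 of BomS1, each exceeded in 1 other female library.

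The tests by splits were written after the counts were seen. Only 1 of 100 splits, the real split, reached the count of the sex comparison (7949 genes, highest other 1). That also held for 2 and 8 h against 0 h in females (1373 and 361, highest other 471 and 1). It held too for 2, 4 and 8 h against 0 h in males (177, 121 and 1433, highest other 43, 18 and 74). Splits that mix sexes or times in a group widen its spread, which lowers their counts by construction. Flies of a time also shared a feeding plate. These splits therefore do not exclude chance on their own, and the 361 fell to 28 without 1 fly. For 8 h against 2 h the count was reached by 2 of 100 in females and 1 of 100 in males. Chance could not be excluded for the DMSO levels in females at 0, 4 and 8 h (100, 96 and 61 of 100 splits reached 1, 1 and 96 genes; highest other 65, 124 and 163) or in males at 0, 4 and 8 h (10, 76 and 21 of 100 reached 7, 150 and 1; highest other 13, 314 and 185). The same held for the female slope (7 of 100, real 1, highest other 1372), where a split far above the real count points to structure of the samples. The splits at 8 h in females and at 4 h in males keep the libraries that stood apart, without which the 96 and 150 fell to 0. A real count of 0 is reached by 100 of 100 splits by construction, so nothing was tested there: DMSO levels at 2 h (highest other 50 in females and 16 in males), the change of the DMSO effect from 0 h (26, 25 and 21 in females and 2 in males), 4 h against 0 h in females (1) and 4 h against 2 h (0 in females and 17 in males). For a DMSO level against none only 10 splits exist, too few to decide: 0.4% gave 47 at 8 h in females (3 of 10, highest other 78) and 132 at 4 h in males (7 of 10, highest other 234), 0.2% in males gave 1 at 0 h (6 of 10, highest other 3) and 1 at 8 h (1 of 10, highest other 0), and 0.1% in males gave 3 at 2 h (1 of 10, highest other 1) and 1 at 8 h (3 of 10, highest other 404). The other 18 gave 0 genes, which all 10 of 10 splits reached, with a highest other of 4.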
